A study of Mus musculus with 924 samples.

How the data were processed

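The samples were 924 single nuclei of mouse hippocampus, sorted into plates and made into libraries by a modified Smart-seq2 protocol, each deposited as 1 sample. According to the submitters' processing notes, reads were aligned to the mm10 transcriptome with Bowtie2 (version not given) and quantified with RSEM 1.27. The deposited values are the natural log of a value on the TPM scale plus 1, as the authors made them, in a table of 25392 genes by 924 nuclei. The natural log was checked on the gaps between the low values of 200 pairs of nuclei, where steps of whole reads at a ratio of 2 were enriched 4.08 times with a natural log and 1.4 times with a log2. The plan had assumed TPM, so values were back-transformed and are written here as value. Their totals per nucleus had a median of 4.42 (2.52 to 21.9) times the total that TPM gives by definition, so a setting with each nucleus rescaled to the TPM total was added. In the table, 1534 genes had a value of 0 in every nucleus.

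Low values were taken to fall on whole multiples of a step, by which reads were recovered for 923 nuclei over 13986 genes. Of the values under 10.5 steps, 68.8% lay within 0.1 of a whole number, where evenly spread values would give 20%. The steps were set from these same low values, which places the lowest ones near 1 by construction. This share is therefore no independent check of the recovered reads. The recovered depth had a median of 73691 reads per nucleus (18460 to 167294, 5th to 95th percentile). A gene counted as detected above a value of 1, or above 10 as an alternative.

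Nuclei were placed in groups by their labels (DG, CA1 and CA2/3 at 12 weeks, sorted DG, sorted CA, 4 weeks, 2 years) and in 15 preparations by the number in their label. Clusters were found with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, anndata 0.12.19) from 2000 variable genes scaled to a maximum of 10, 20 principal components, 15 neighbours, a resolution of 1.0 and seed 0. Each cluster was named by 25 fixed marker lists. A marker counted with detection in at least 30% of the nuclei, at least 3 markers were needed, and the thresholds on scores (1.5 and 0.5) were set after the clusters had been seen. Of all nuclei, 547 were in granule-like clusters. Of all nuclei, 98 carried at least 5 markers of 2 classes, as joined nuclei would, and were kept. GABAergic-like nuclei were clustered again with 10 principal components at a resolution of 0.8. Clusters 6 and 7, pyramidal-like, had 0 own markers among their 10 leading genes, so pyramidal-like shares are not compared between groups.

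Genes were tested with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) on the mean of log2(value + 1) over the nuclei of each preparation, with a trend in the variance, 2-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05. All folds are on that log2(value + 1) scale. Where a fold is given relative to the median of all genes, its SE and p are those of the fold before that shift, tested against 0. A gene was tested if detected in at least 20% of the nuclei of at least 1 preparation, and a preparation needed at least 10 nuclei. The 3 fits were the regions (8 preparations, excitatory-like nuclei), sorted against unsorted DG (6 preparations, all nuclei) and age (8 preparations, granule-like nuclei). With 1 preparation of a pair left out, the lone preparation is assumed to vary like the other groups. The 31 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 3 members had been tested. Camera compares a list with all other genes, and fry tests whether a list's genes move 1 way or, in its mixed form, either way. Shares of classes were compared by exact permutation of preparations, 2-sided, and neuronal with glial-like nuclei by exact sign flips, in preparations with at least 5 nuclei of both kinds. Intervals are 95% Wilson intervals, and a share of 0 is given the limit that 3 nuclei would make.

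Named genes are the 8 with the largest fold in each direction among called genes whose preparations do not overlap, up to 4 members of each list past the threshold, and members of the lists that name a region or class. Symbols without a name of function and sex-linked genes were left out. This rule, the comparisons, the gene lists, the filters and the first set of other settings were fixed before the data were examined. That set was the log2 of the mean value, a pseudocount of 10, no filter, a filter at 50% of nuclei, quantile normalization, the number of detected genes as a covariate, the preparation number as a replicate block, all nuclei, a resolution of 0.6, a minimum of 2000 genes, the sets labelled DG alone, classes by the mean of scaled markers and leaving out each preparation in turn. Settings added after seeing the data were rescaling to TPM totals, a minimum of 4000 genes, recovered depth as a covariate, granule-like against pyramidal-like nuclei, granule-like nuclei alone or without GABAergic-like ones in the sorted comparison, leaving out the preparations numbered 3, thinning to 20000 recovered reads, and fry in either direction.

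The fits were tested on simulated data drawn from the mean and the fitted variance of each gene, with 200 genes shifted per comparison. A shift of 4 on the log2 scale was recovered for 93.9% to 100% of genes, of 2 for 31.3% to 70.2% and of 1 for 1.49% to 11.9%. Per comparison, 3 to 13 unchanged genes were called among 87 to 126 calls in all. The highest were 13 of 114 calls for 2 years against 4 weeks and 10 of 110 for DG against CA1. Each gene was drawn independently, so the simulation holds no correlation between genes and does not test the lists for it. Coordinates are from GENCODE vM21 on GRCm38, in which 23909 of the 25392 symbols were found. Figures were drawn with matplotlib 3.10.9. The 22 sorted CA nuclei, 1 preparation, entered no fit across genes. Raw reads were not used here.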

Results

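RNA was measured in 924 single nuclei from mouse hippocampus, each sequenced as a full-length cDNA library. C57BL/6 mice gave nuclei at 12 weeks, at 4 weeks (113 nuclei) and at 2 years (135 nuclei), and vGAT-Cre mice (strain label vGAT-Cre, Slc32a1tm2(cre)Lowl) gave 155 nuclei at 12 weeks. The 12-week C57BL/6 nuclei came from dissected dentate gyrus (DG, 305 nuclei in 4 preparations), CA1 (99 nuclei in 2 preparations) and CA2/3 (117 nuclei in 2 preparations). The vGAT-Cre mice received, by virus, a Cre-dependent fluorescent tag of the nuclear envelope. Their nuclei were sorted from DG (133 nuclei in 2 preparations) or from CA1, CA2 and CA3 together (22 nuclei in 1 preparation). Titles of the CA nuclei alone name GFP, and the labels do not say that each sorted DG nucleus carried the tag. At 4 weeks, 35 nuclei were labelled DG and 78 carried no region label. At 2 years, 63 nuclei carried no region label and 72 were labelled DG. A preparation is the set of nuclei of 1 group whose labels share a number. The labels do not say whether the number counts animals, so the p-values measure only the spread between preparations, which may be technical.

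A nucleus had a median of 4882.5 genes with a value above 1, with a range of 2022 to 8008. Reads recovered from the steps of low values had a median of 73691 per nucleus. By preparation, the median of recovered reads ran from 47261 in sorted CA nuclei to 136824 in 2-year preparation 2, and the median number of genes ran from 3732.5 to 6139.5. The 95% Wilson intervals and the limits for counts of 0 given for shares cover counting error only.

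Clustering parted the nuclei into 12 clusters, named by markers fixed beforehand. Granule-like nuclei formed the largest class. The others were 167 pyramidal-like, 112 GABAergic-like, 51 astrocyte-like, 17 oligodendrocyte-like, 17 oligodendrocyte precursor-like and 13 microglia-like nuclei. The question for the adult C57BL/6 tissue was which classes each dissection holds. Excitatory-like nuclei, granule-like and pyramidal-like together, made up 91.4% ± 7.36 (SD, n = 4) of nuclei in DG and 73.1% ± 0.539 (SD, n = 4) in the CA preparations. Glial-like nuclei made up 3.78% ± 3.72 (SD, n = 4) in DG and 17.3% ± 3.27 (SD, n = 4) in CA. Both differences had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 preparations allow. The 4 CA preparations are 2 of CA1 and 2 of CA2/3, and they carry only the numbers 1 and 3. If a number marks 1 animal they are not independent, while the permutation treats them as if they were. In nuclei with at least 4000 genes the shares were 91.8% and 79.8% for excitatory-like and 2.49% and 9.50% for glial-like nuclei, with the same exact permutation p. GABAergic-like nuclei made up 4.82% ± 3.92 in DG and 9.56% ± 2.85 in CA (exact permutation p = 0.143, SD, n = 4 each). In DG preparation 2 all 40 nuclei were granule-like, and 0 of 40 GABAergic-like nuclei allows a share of up to 7.5%. Without any 1 of the CA preparations (CA1 1, CA1 3, CA2/3 1 or CA2/3 3), the exact permutation p for excitatory-like nuclei was 0.0571.

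**Figure D1:**
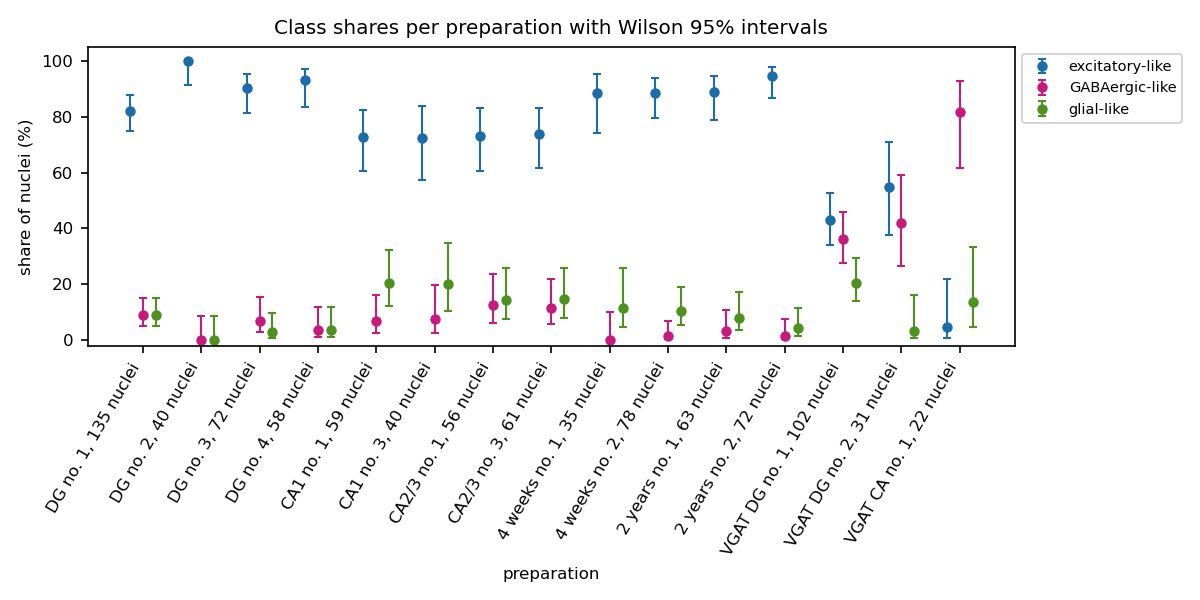
Shares of excitatory-like, GABAergic-like and glial-like nuclei, in percent of all nuclei, with 1 point per class for each of the 15 preparations and bars for the 95% Wilson interval. GABAergic-like nuclei reached 81.8% in the sorted CA nuclei, and glial-like nuclei averaged 3.78% in DG and 17.3% in CA.

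Neuronal and glial-like nuclei differed in the number of genes detected. Neuronal nuclei held 1842 ± 690 more genes (mean difference of medians ± SD, n = 8 preparations) and were higher in 8 of 8 preparations (two-sided exact sign-flip permutation p = 0.00781, the smallest possible). Among these preparations, DG, CA1 and CA2/3 share the number 1, and CA1 and CA2/3 the number 3. If a number marks 1 animal they are not independent, while the sign flips treat them as if they were. The median was 4837 genes in granule-like, 5702 in pyramidal-like, 4750.5 in GABAergic-like, 3464 in astrocyte-like and 2839 in microglia-like nuclei. After thinning each nucleus to 20000 recovered reads the difference was 1317 ± 487 genes (SD, n = 8).

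The comparison of DG with CA1 asked which genes part the excitatory-like nuclei of the regions. These pools were mixed. Granule-like nuclei were 9 of 43 and 3 of 29 excitatory-like nuclei in CA1 preparations 1 and 3. In CA2/3 preparations 1 and 3 they were 3 of 41 and 11 of 45. In DG preparation 1, 19 of 111 were pyramidal-like. The folds between regions are those of the mixed pools. The median of all 11324 tested genes lay at -0.50 on the log2(value + 1) scale, DG minus CA1, so differences are given relative to that median. SEs, p-values, means and counts of called genes belong to the values before this shift. Prox1, the homeobox factor of granule neurons (chromosome 1, 190118035 to 190170714, GRCm38), was higher in DG by 7.98 (SE 0.81, limma adjusted p = 0.00019, n = 4 against 2). C1ql2, a secreted synaptic protein of the C1q family, was higher by 7.78 (SE 0.66, limma adjusted p = 8.31e-05), with means of 9.47 ± 0.40 (SD, n = 4) in DG and 2.19 ± 0.62 (SD, n = 2) in CA1. The Purkinje cell protein gene Pcp4 (7.94), the semaphorin gene Sema5a (7.21) and the synaptic vesicle gene Synpr (7.01) were also higher in DG, as were Fam163b (6.53), the zinc finger gene Glis3 (6.28) and the Notch coactivator gene Maml2 (5.82). Lower in DG were the copine gene Cpne7 at -8.36 (SE 0.99, limma adjusted p = 0.000206), Mpped1 at -7.09 (SE 0.52, limma adjusted p = 8.43e-06; chromosome 15, 83779467 to 83858494), the synaptic vesicle gene Sv2b at -6.59 and the seizure-related gene Sez6 at -5.77. The pyramidal neuron factor Neurod6 lay at -5.49, the secreted protein gene Dkk3 at -5.60, the teneurin gene Tenm4 at -5.31 and the neuronal tubulin gene Tubb3 at -5.27. Each DG preparation lay beyond each CA1 preparation for these genes.

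Of the gene lists, dentate granule markers were higher in DG for 13 of 14 members (14 adjusted over the list alone; camera adjusted p = 1.65e-29, adjusted p = 0.225 with an estimated correlation), among them Stxbp6 (5.67) and C1ql3 (5.57). CA1 markers were lower in DG for 9 of 10 (9 adjusted over the list alone; camera adjusted p = 1.09e-08, adjusted p = 0.548 with an estimated correlation), with the matricellular gene Nov at -3.33 and Wfs1 of the endoplasmic reticulum at -3.54. Immediate early genes, which neuronal activity induces, were lower in DG for 11 of 16 and higher for 1 (the same counts adjusted over the list alone; camera adjusted p = 0.000947, adjusted p = 0.624 with an estimated correlation). Arc lay at -4.34 (SE 0.54, limma adjusted p = 0.000206). Nr4a1 lay at -3.69, Dusp1 at -2.38 and Fos at -1.57. Jun, chosen after its values were seen, was the member higher in DG, by 3.42 before the shift is taken off (SE 0.65, limma adjusted p = 0.0046). Calcium-binding protein genes moved up on balance, with 3 of 16 higher and 1 lower in DG (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.42e-07, adjusted p = 0.624 with an estimated correlation). The calcium sensor gene Ncald was higher by 5.58 and the calcium buffer gene Calb1 by 4.77, and the kinase gene Camk4 was lower, at -2.28. Cytosolic ribosomal protein genes had 0 of 36 members past the limma threshold (0 adjusted over the list alone; 8 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 1.43e-11 upwards, adjusted p = 0.624 with an estimated correlation), with Rplp1 at 4.10 (SE 1.12, limma adjusted p = 0.052).

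Between DG and CA1, limma called 1314 genes, 246 higher and 1068 lower in DG (two-sided, Benjamini-Hochberg adjusted p under 0.05). The share of called genes that were higher in DG was 18.7% with the values as deposited, 48.7% after quantile normalization, which removes the shift of the median, 37.1% with the log2 of the mean in place of the mean log2 and 58.95% with the number of detected genes as a covariate. It was 30.3% without CA1 preparation 1, 7.99% without CA1 preparation 3 and 32.4% over all nuclei. In percent of the reported count, 60.2%, 50.4%, 48.4% and 58.9% as many genes were called without DG preparations 1, 2, 3 and 4, 153.3% and 153.6% without CA2/3 preparations 1 and 3, and 19.7% with the log2 of the mean. The call for Camk4 ended without DG preparation 2 or 3 or CA1 preparation 1, and with the number of detected genes as a covariate, all nuclei, or nuclei with at least 4000 genes. With the log2 of the mean the calls for C1ql2, Calb1, Camk4, Cpne7, Glis3, Mpped1, Nov, Sv2b, Synpr and Jun ended (limma adjusted p = 0.0786 for Jun).

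**Figure D2:**
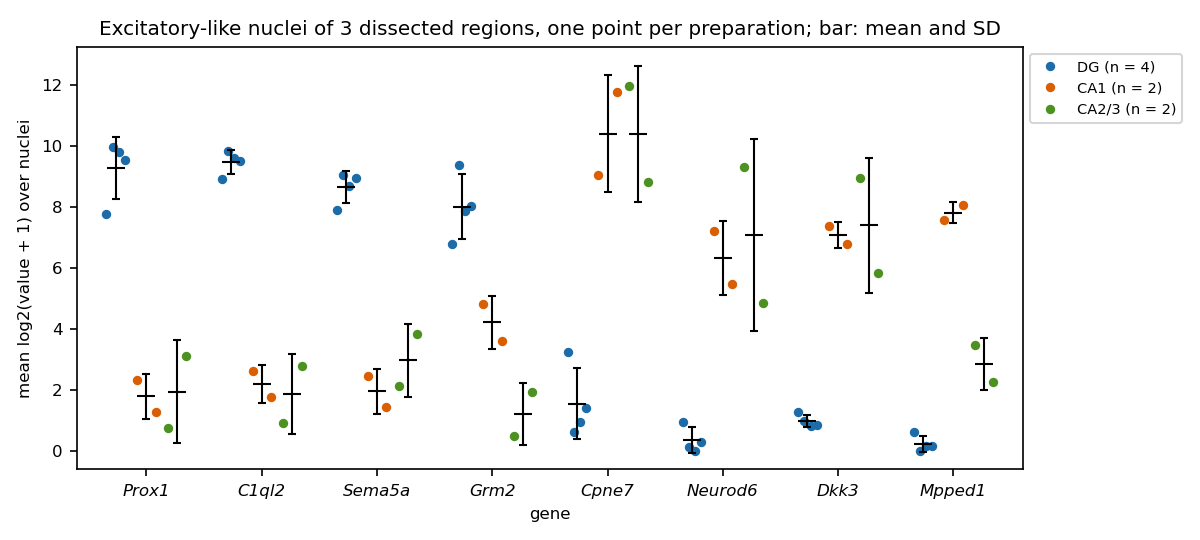
Mean log2(value + 1) over the excitatory-like nuclei of each adult preparation for genes that part the regions, with 1 point per preparation (DG n = 4, CA1 n = 2, CA2/3 n = 2) and bars for the mean and SD. C1ql2 averaged 9.47 in DG and 2.19 in CA1.

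DG and CA2/3 were parted by many of the granule neuron genes above and by pyramidal genes of CA2/3. The median of all tested genes lay at -0.42, DG minus CA2/3, and differences are given relative to it, with SEs, p-values and counts from before this shift. C1ql2 was higher in DG by 8.03 (SE 0.66, limma adjusted p = 0.000189, n = 4 against 2), Prox1 by 7.75, the metabotropic glutamate receptor gene Grm2 by 7.23 (SE 0.76, limma adjusted p = 0.000733), C1ql3 by 7.20 and the adenylyl cyclase gene Adcy1 by 6.22. Fam163b (6.64), Pcp4 (6.53) and Glis3 (6.15) were also higher in DG. Lower in DG were Cpne7 at -8.43 (SE 0.99, limma adjusted p = 0.000733), Sv2b at -6.47, Neurod6 at -6.32 and Dkk3 at -6.00. The RNA-binding protein gene Khdrbs3 (-5.48), the receptor kinase gene Kit (-5.38), the cytokine signalling inhibitor gene Socs2 (-5.28) and the growth cone gene Stmn2 (-5.26) were lower as well. Each DG preparation lay beyond each CA2/3 preparation for these genes.

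Dentate granule markers were higher in DG for 13 of 14 (14 adjusted over the list alone; camera adjusted p = 9.34e-31, adjusted p = 0.207 with an estimated correlation), among them Lct at 5.05. CA3 markers were lower in DG for 7 of 9 (8 adjusted over the list alone; camera adjusted p = 9.12e-06, adjusted p = 0.695 with an estimated correlation). Among them the proteoglycan gene Spock1 lay at -4.58 (SE 0.68, limma adjusted p = 0.00116), the nectin gene Pvrl3 at -3.09, the repressor gene Trps1 at -2.60 and the zinc finger gene Plagl1 at -1.92. Voltage-gated potassium channel genes had 1 member higher, Kcnc4 at 4.95, and 2 lower in DG, Kcnc2 at -4.64 and Kcnq5 at -2.75, of 20 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00108 upwards, adjusted p = 0.695 with an estimated correlation). Calcium-binding protein genes had 4 of 16 higher and 1 lower (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.93e-07 upwards, adjusted p = 0.695 with an estimated correlation). Calb1 was higher by 5.48, Ncald by 3.71 and Camk2b by 1.89, and Camk4, named after its values were seen, lay at -2.41 before the shift is taken off (SE 0.66, limma adjusted p = 0.0416). Excitatory neuron markers had 1 higher, Grm2, and 1 lower, Neurod6, of 7 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0242 upwards, adjusted p = 0.695 with an estimated correlation). Cytosolic ribosomal protein genes had 0 of 36 past the limma threshold (0 adjusted over the list alone; 13 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 1.39e-13 upwards, adjusted p = 0.695 with an estimated correlation).

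Between DG and CA2/3, limma called 887 genes, 218 of them higher in DG. The share higher in DG was 24.6% as deposited, 52.9% after quantile normalization, 51.1% with the log2 of the mean, 60.9% with the number of detected genes as a covariate, and 46.6% and 13.02% without CA2/3 preparations 1 and 3. In percent of the reported count, 52.8%, 42.7%, 37.9% and 46.7% as many genes were called without DG preparations 1 to 4 in turn, 49.6% and 161.9% without CA2/3 preparations 1 and 3, and 151.7% without CA1 preparation 3. The calls ended for Plagl1 without CA2/3 preparation 1 or DG preparation 2 or 4, for Camk2b without CA2/3 preparation 3 or DG preparation 2, 3 or 4, and for Camk4 without any 1 DG preparation or CA2/3 preparation 1. Of the 27 called genes that the naming rule takes, 17 lost the call with the log2 of the mean.

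CA1 and CA2/3, compared with n = 2 preparations each, had few genes past the threshold. Their pyramidal-like nuclei fell into clusters mainly by preparation number. A lean by region was seen in preparations 3 but not in preparations 1. Cluster 7 held 23 and 27 nuclei of CA1 and CA2/3 preparations 1, and 10 and 5 of preparations 3. Cluster 6 held 11 and 11 of preparations 1, and 16 and 29 of preparations 3. With preparations of a region this unlike, few calls do not show that the regions are alike. Mpped1 was higher in CA1 by 4.96 (SE 0.60, limma adjusted p = 0.00533), with means of 7.82 ± 0.34 and 2.86 ± 0.86 (SD, n = 2 each). The latrophilin gene Lphn2 was higher by 4.00 (SE 0.48, limma adjusted p = 0.00533), with means of 5.34 ± 0.63 and 1.34 ± 0.25. The potassium channel gene Kcnh7 (4.01), the heparan sulfate enzyme genes Hs6st3 (3.63), Ndst3 (3.43) and Hs6st2 (2.71), the adenylyl cyclase gene Adcy8 (3.27) and the membrane-remodelling gene Fnbp1l (3.11) were also higher in CA1. Lower in CA1 were Ccbe1 at -3.92 (SE 0.68, limma adjusted p = 0.0454) and the interferon-inducible gene Mndal at -2.08 (SE 0.34). The preparations of CA1 and CA2/3 did not overlap for these genes.

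CA1 markers were higher in CA1 for 3 of 10 (6 adjusted over the list alone; camera adjusted p = 6.94e-12, adjusted p = 0.360 with an estimated correlation), with Mpped1 and Nov (2.56) among them. CA3 markers had 0 of 9 past the limma threshold (7 lower adjusted over the list alone; 7 lower at an unadjusted p under 0.05; camera adjusted p = 9.93e-10 downwards, adjusted p = 0.360 with an estimated correlation), with Trps1 at -2.67 (limma adjusted p = 0.11) and Pvrl3 at -2.85 (limma adjusted p = 0.135). Immediate early genes had 0 of 16 (6 higher adjusted over the list alone; 6 higher at an unadjusted p under 0.05; camera adjusted p = 3.8e-06 upwards, adjusted p = 0.531 with an estimated correlation), with Fos at 1.53 (limma adjusted p = 0.0906). Metabotropic glutamate receptor genes had 0 of 6 by limma (3 higher and 1 lower both adjusted over the list alone and at an unadjusted p under 0.05; camera adjusted p = 0.0431 upwards, adjusted p = 0.406 with an estimated correlation). GABA-A receptor genes had 0 of 11 (0 adjusted over the list alone; 3 higher at an unadjusted p under 0.05; camera adjusted p = 0.0276 upwards, adjusted p = 0.718 with an estimated correlation). Neuropeptide and neurotrophin genes had 0 of 8 (0 adjusted over the list alone; 2 higher at an unadjusted p under 0.05; camera adjusted p = 0.0321 upwards, adjusted p = 0.531 with an estimated correlation).

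Between CA1 and CA2/3, limma called 19 genes, 16 higher and 3 lower in CA1. With the log2 of the mean it called 0, where 5.88% of the tested genes had an unadjusted p under 0.05. The share of called genes higher in CA1 was 84.2% as deposited, 68.97% after quantile normalization, 53.7% with the number of detected genes as a covariate and 24.3% without CA2/3 preparation 3. The count was 2 without any 1 DG preparation, which left the calls for Mpped1 and Lphn2, and 7, 44 and 74 without CA2/3 preparation 1, CA1 preparation 3 and CA2/3 preparation 3. Of the 13 called genes that the naming rule takes, 5 lost the call without CA1 preparation 1, 5 without CA1 preparation 3, 8 without CA2/3 preparation 1, 2 without CA2/3 preparation 3 and 10 with recovered depth as a covariate.

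The sort of nuclei from the vGAT-Cre mice, which were given the tag by virus, was made to enrich GABAergic neurons. GABAergic-like nuclei made up 36.3% (95% interval 27.6 to 46.0) of VGAT DG preparation 1, 41.9% (26.4 to 59.2) of VGAT DG preparation 2 and 81.8% (61.5 to 92.7) of the sorted CA nuclei, where unsorted DG averaged 4.82% ± 3.92 and unsorted CA 9.56% ± 2.85 (SD, n = 4 each). Granule-like nuclei were the largest class in VGAT DG preparations 1 and 2, at 42.2% and 45.2%, and glial-like nuclei made up 20.6% and 3.23%. The VGAT DG nuclei, averaged over all classes, were compared with unsorted adult DG, which differs from them in strain, virus, sort and class composition at once. The median of all 10374 tested genes lay at -0.30, VGAT minus unsorted, and differences are given relative to it. Again SEs, p-values, means and counts are from before the shift. The zinc finger gene Zfp949 (chromosome 9, 88548020 to 88571061) was higher in VGAT DG by 6.36 (SE 0.57, limma adjusted p = 3.34e-07, n = 2 against 4) and the intermediate filament gene Vim by 5.51 (SE 0.50, limma adjusted p = 3.45e-07). The nesprin gene Syne2 was higher by 4.47 (SE 0.64, limma adjusted p = 5.01e-05), with means of 5.45 ± 2.49 (SD, n = 2) and 1.28 ± 0.15 (SD, n = 4). Lower were Olfm1, which encodes a secreted olfactomedin, at -5.90 (SE 0.39, limma adjusted p = 8.98e-10), Pcp4 at -6.93, C1ql3 at -6.40 and C1ql2 at -5.92. The preparations of both groups did not overlap for these genes.

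GABAergic neuron markers were higher in VGAT DG for 7 of 8 members (7 adjusted over the list alone; camera adjusted p = 1.41e-08, adjusted p = 0.252 with an estimated correlation). The GABA-synthesising enzyme gene Gad2 was higher by 3.51 (SE 0.44, limma adjusted p = 1.31e-05; 4.09 ± 0.13 against 0.89 ± 0.56, SD, n = 2 and 4), Dlx6os1 by 3.58, Erbb4 by 2.89 and the homeobox gene Dlx1 by 2.56. Interneuron subtype markers had 3 of 9 higher, Reln (2.65), Nxph1 (2.46) and Lhx6 (1.55), and 1 lower, Cck at -4.45 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0201 upwards, adjusted p = 0.373 with an estimated correlation). Dentate granule markers were lower for 13 of 13 (13 adjusted over the list alone; camera adjusted p = 7.45e-08, adjusted p = 0.373 with an estimated correlation), and excitatory neuron markers for 5 of 5 (5 adjusted over the list alone; camera adjusted p = 5.58e-05, adjusted p = 0.343 with an estimated correlation), with Nrgn at -5.50, Neurod2 at -4.55 and the vesicular glutamate transporter gene Slc17a7 at -3.42. Calcium-binding protein genes were lower for 14 of 16 (15 adjusted over the list alone; camera adjusted p = 9.36e-13, adjusted p = 0.252 with an estimated correlation), among them Hpca at -5.31. Synaptic vesicle and release genes were lower for 15 of 29 (16 adjusted over the list alone; camera adjusted p = 0.000266, adjusted p = 0.343 with an estimated correlation), with Cplx2 at -3.88 and Syn2 at -3.09.

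Housekeeping and stress lists, and lists of channel, neuropeptide and neurotrophin genes, were lower in VGAT DG too. Cytosolic ribosomal protein genes were lower for 30 of 36 (32 adjusted over the list alone; camera adjusted p = 7.07e-14, adjusted p = 0.252 with an estimated correlation), with Rpl8 at -5.28 and Rpl3 at -3.78 relative to the median. Oxidative phosphorylation genes were lower for 30 of 41 (31 adjusted over the list alone; camera adjusted p = 1.83e-09, adjusted p = 0.373 with an estimated correlation), with Cox6a1 at -5.13. Heat shock and stress genes were lower for 7 of 13 (9 adjusted over the list alone; camera adjusted p = 0.000686, adjusted p = 0.373 with an estimated correlation), with Hsp90aa1 at -2.92. Voltage-gated potassium channel genes were lower for 11 of 20 and higher for 3 (the same counts adjusted over the list alone; camera adjusted p = 0.0191 downwards, adjusted p = 0.417 with an estimated correlation). Kcnip2 lay at -4.44 and Kcnc2 at 2.74, and the other higher members, named after their values were seen, were Kcnip1 at 1.51 (SE 0.34) and Kcnh7 at 1.52 (SE 0.53) before the shift is taken off. Voltage-gated calcium and sodium channel genes were lower for 11 of 18 (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0255, adjusted p = 0.498 with an estimated correlation), with Scn2b at -5.20. Neuropeptide and neurotrophin genes were lower for 5 of 6 (6 adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.252 with an estimated correlation), with Bdnf at -2.71. The call for Kcnh7 ended without DG preparation 1 or 4 or VGAT DG preparation 1 or 2.

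Between VGAT DG and unsorted DG, limma called 2943 genes, 703 higher and 2240 lower. The share higher in VGAT DG was 23.9% as deposited, 51.7% after quantile normalization, 44.3% in nuclei with at least 4000 genes, 14.1% with the filter at 50% of nuclei and 10.96% in granule-like nuclei alone. In percent of the reported count, 55.5% as many genes were called without VGAT DG preparation 2, 41.05% with the log2 of the mean, 28.4% with the number of detected genes as a covariate and 61.98% in granule-like nuclei alone. The call for Lhx6 ended without DG preparation 3 or 4, those for Syne2 and Bdnf ended with the number of detected genes as a covariate, and that for Reln ended in granule-like nuclei alone. Of the 59 called genes named for this comparison, 16 lost the call with the log2 of the mean, Gad2, Dlx1, Erbb4, Reln and Nxph1 among them. The median log2 difference of GABAergic neuron markers, before the shift is taken off, was 3.14 with it and 2.43 without.

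Interneuron markers, read as the share of GABAergic-like nuclei with a value above 1, served to describe the sorted interneurons. In VGAT DG preparation 1 the secreted protein gene Reln was found in 25 of 37 nuclei, 67.6% (95% Wilson interval 51.5 to 80.4), and in 3 of 43 granule-like nuclei of the same preparation. The neurexophilin gene Nxph1 was found in 25 of 37 and 1 of 43, the homeobox gene Lhx6 in 24 of 37 and 1 of 43, and the neuropeptide gene Npy in 15 of 37 and 1 of 43. Adarb2 was found in 18 of 37 GABAergic-like and in 30 of 43 granule-like nuclei, so its share does not exceed that background. In VGAT DG preparation 2, with 13 GABAergic-like nuclei, Cnr1 was found in 8 and in 2 of 14 granule-like nuclei, Vip in 4 and 1, Adarb2 in 10 and 9 and Reln in 5 and 4, with overlapping 95% intervals for each of them. Sst was found in 8 of 37 nuclei in VGAT DG preparation 1 and 0 of 13 in preparation 2, which allows a share of up to 23.1%. In the sorted CA nuclei Nxph1 was found in 12 of 18, Reln in 9 and Kit in 7. The median number of genes was 4750.5 in GABAergic-like and 4837 in granule-like nuclei over all preparations.

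**Figure D3:**
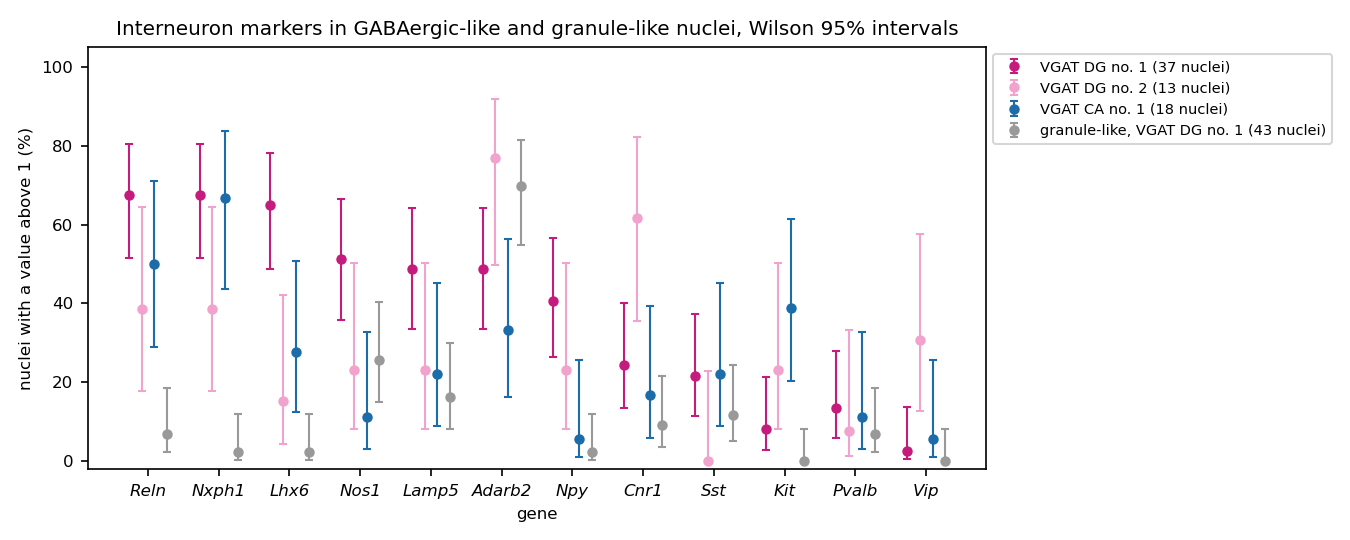
Share of nuclei with a value above 1, in percent, for interneuron markers in GABAergic-like nuclei of the sorted preparations and granule-like nuclei of VGAT DG preparation 1, with 95% Wilson intervals. Reln reached 67.6% of 37 GABAergic-like nuclei in VGAT DG preparation 1.

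The age series asked how granule-like nuclei change from 4 weeks to 12 weeks and 2 years. Cluster 4 held 102 nuclei. Of these, 24 and 62 came from 4-week preparations 1 and 2, and 10 and 1 from the 2-year preparations. Its leading genes were Penk, Col6a1, Rgs4 and Necab3. Between 12 and 4 weeks, the opioid peptide gene Penk (chromosome 4, 4133531 to 4138819) was lower at 12 weeks at -9.32 (SE 0.53, limma adjusted p = 1.14e-14, n = 4 against 2), with means of 0.35 ± 0.16 (SD, n = 4) and 9.67 ± 0.19 (SD, n = 2). The collagen gene Col6a1 (chromosome 10, 76708792 to 76726168) lay at -9.34 (SE 0.54, limma adjusted p = 1.14e-14), Necab3 at -7.64, the G protein regulator gene Rgs4 at -7.32 and Stmn2 at -5.47. Higher at 12 weeks were the axon guidance gene Slit1 by 6.77 (SE 0.63, limma adjusted p = 2.82e-09), the peptide gene Cck by 6.46, Calb1 of mature granule neurons by 5.29 (SE 0.62, limma adjusted p = 4.13e-07; 8.36 ± 0.58 against 3.07 ± 0.22, SD, n = 4 and 2), the sodium channel subunit gene Scn3b by 5.11 and the calcium release channel gene Ryr1 by 4.83. The preparations of both ages did not overlap for these genes.

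Immature neuron and neurogenesis genes fell from 4 to 12 weeks for 8 of 17 (8 adjusted over the list alone; camera adjusted p = 0.000647, adjusted p = 0.1998 with an estimated correlation), with Stmn1 at -3.37, Tubb3 at -3.17 and Igfbpl1 at -1.81. Dentate granule markers were higher at 12 weeks for 9 of 14 (9 adjusted over the list alone; camera adjusted p = 2.67e-07, adjusted p = 0.1998 with an estimated correlation), with Maml2 by 4.02 and Glis3 by 3.83. Ionotropic glutamate receptor genes were higher for 6 of 13 (9 adjusted over the list alone; camera adjusted p = 3.83e-05, adjusted p = 0.1998 with an estimated correlation), among them Grin2a by 3.02 (SE 0.47, limma adjusted p = 3.68e-05) and Gria1 by 1.75. Calcium-binding protein genes were higher for 5 of 16 (6 adjusted over the list alone; camera adjusted p = 1.45e-05, adjusted p = 0.401 with an estimated correlation), Calb1 among them. Calcium and sodium channel genes had 6 of 19 higher and 1, Cacna2d2 at -3.21, lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00201 upwards, adjusted p = 0.498 with an estimated correlation). Potassium channel genes had 3 of 18 higher, among them Kcnip2 by 2.96, and 1, Kcnip3 at -3.10, lower (the same counts adjusted over the list alone; camera adjusted p = 0.0047 upwards, adjusted p = 0.498 with an estimated correlation). Immediate early genes were lower at 12 weeks for 4 of 11 (4 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.1998 with an estimated correlation), with the pentraxin gene Nptx2 at -3.56 and Arc at -1.48. Genes of antigen presentation, complement and interferon were lower for 2 of 6, H2-D1 at -2.36 and H2-K1 at -1.86 (3 adjusted over the list alone; camera adjusted p = 0.00453, adjusted p = 0.1998 with an estimated correlation).

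Smaller groups also passed camera between 12 and 4 weeks. Neuropeptide and neurotrophin genes had 1 higher, Cck, and 4 lower of 9, among them Penk, Chgb at -2.81 and Bdnf at -2.93 (2 and 6 adjusted over the list alone; camera adjusted p = 0.00698 downwards, adjusted p = 0.1998 with an estimated correlation). Interneuron subtype markers had 3 of 5 higher, Cck, Lamp5 and Adarb2 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0119, adjusted p = 0.1998 with an estimated correlation). Excitatory neuron markers had 2 of 5 higher, Camk2a and Grm2 (3 adjusted over the list alone; camera adjusted p = 0.00385, adjusted p = 0.438 with an estimated correlation), and CA1 markers had 1 of 3, Fibcd1 by 2.75 (1 adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.312 with an estimated correlation). Cytosolic ribosomal protein genes were lower for 3 of 36, Rps7 at -2.14, Rps18 at -2.37 and Rps9 at -2.06 (3 adjusted over the list alone; camera adjusted p = 0.00836, adjusted p = 0.699 with an estimated correlation). The calls ended for Lamp5, Chgb, Bdnf, Rps7, Rps9, Rps18 and Adarb2 without 4-week preparation 1, and for Adarb2, Grm2 and Rps18 without 4-week preparation 2. They ended for Adarb2 without any 1 DG preparation, for Rps9 without DG preparation 1, 2 or 4, for Rps18 without 2 or 4, for Rps7 without 2, and for Grm2 without 2, 3 or 4. With the log2 of the mean the calls for Rps7, Rps9, Rps18 and Grm2 ended. Those for Rps7 and Rps9 also ended with the number of detected genes as a covariate and with rescaling to TPM totals.

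Between 12 and 4 weeks, limma called 1071 genes, 451 higher and 620 lower at 12 weeks. The share higher at 12 weeks was 42.1% as deposited, 61.7% with the log2 of the mean and 63.9% with the number of detected genes as a covariate. It was 21.2% with no filter on low values, 22.9% without 4-week preparation 2 and 25.1% with the sets labelled DG alone. In percent of the reported count, 53.8% as many genes were called without 4-week preparation 1 and 38.9% with recovered depth as a covariate. That covariate ended the calls of 17 of the 51 called genes named for this comparison, Arc, Fibcd1, Gria1, Kcnip3 and Stmn1 among them.

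**Figure D4:**
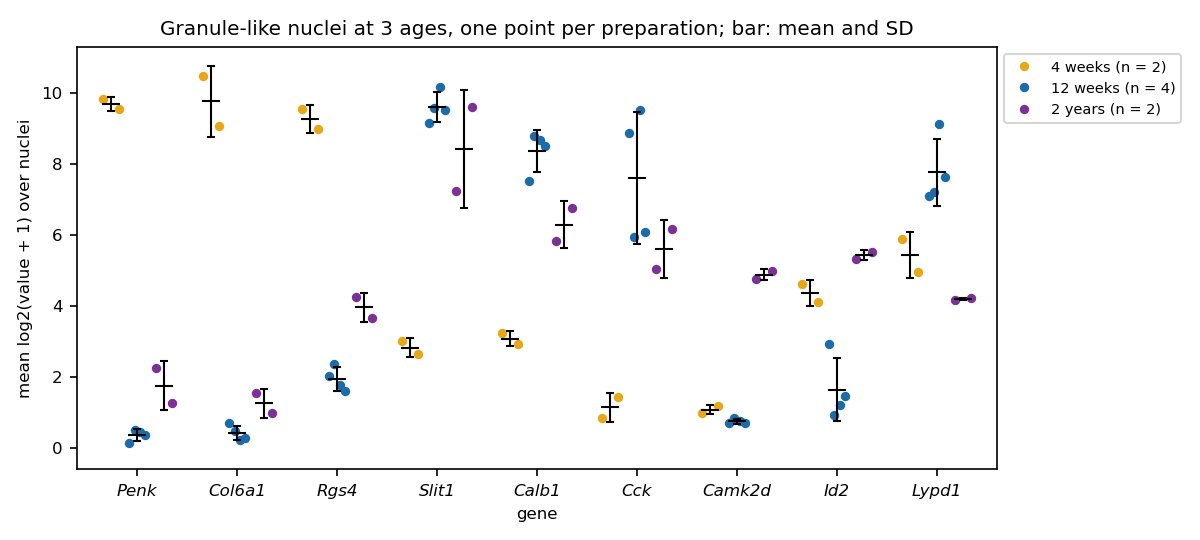
Mean log2(value + 1) over granule-like nuclei of each preparation by age (4 weeks n = 2, 12 weeks n = 4, 2 years n = 2) for genes that differ with age, with 1 point per preparation and bars for the mean and SD. Penk averaged 9.67 at 4 weeks and 0.35 at 12 weeks.

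Between 2 years and 4 weeks, Col6a1 was lower at 2 years at -8.50 (SE 0.62, limma adjusted p = 2.59e-11, n = 2 each). Penk lay at -7.92 (SE 0.61, limma adjusted p = 5.85e-11), with means of 1.75 ± 0.70 and 9.67 ± 0.19 (SD, n = 2 each). Lower as well were Stmn2 at -6.86, Necab3 at -6.15 and Rgs4 at -5.30, and the collagen gene Col27a1 at -4.76. Higher at 2 years were Slit1 by 5.59 (SE 0.72, limma adjusted p = 4.92e-06), the adaptor gene Nos1ap by 4.80, Lct by 4.07, the kinase gene Camk2d by 3.80 (SE 0.47, limma adjusted p = 2.7e-06) and Scn3b by 3.78. The preparations of both ages did not overlap for these genes. Most 4-week granule-like nuclei lay in cluster 4, as above.

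Immature neuron and neurogenesis genes were lower at 2 years than at 4 weeks for 6 of 17 (9 adjusted over the list alone; camera adjusted p = 6.84e-09, adjusted p = 0.140 with an estimated correlation), with Dpysl3 at -1.97 and Igfbpl1 at -1.87. Immediate early genes were lower for 3 of 11 (3 adjusted over the list alone; camera adjusted p = 0.00121, adjusted p = 0.172 with an estimated correlation), Nptx2 at -2.91, Fosl2 at -2.21 and Arc at -1.30. Genes of antigen presentation, complement and interferon were lower for 2 of 6, H2-D1 at -1.78 and H2-K1 at -1.46 (2 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.267 with an estimated correlation). Dentate granule markers were higher for 4 of 14 (5 adjusted over the list alone; camera adjusted p = 6.2e-06, adjusted p = 0.364 with an estimated correlation), Lct and Trpc6 (2.73) among them. Calcium-binding protein genes were higher for 2 of 16, Calb1 by 3.21 (SE 0.72, limma adjusted p = 0.00902) and Camk2a by 1.75 (6 adjusted over the list alone; camera adjusted p = 1.28e-05, adjusted p = 0.463 with an estimated correlation). GABA-A receptor genes were higher for 2 of 9, Gabrd by 3.48 and Gabra5 by 3.08 (3 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.528 with an estimated correlation). Interneuron subtype markers had 3 of 5 higher, Cck by 4.46, Lamp5 by 2.47 and Adarb2 by 2.48 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.267 with an estimated correlation). Excitatory neuron markers had 1 of 5 higher, Camk2a (2 adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.548 with an estimated correlation), and ionotropic glutamate receptor genes 1 of 13, Grin2a by 2.20 (1 adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.528 with an estimated correlation). Oxidative phosphorylation genes had 0 of 41 by limma (0 adjusted over the list alone; 8 higher at an unadjusted p under 0.05; camera adjusted p = 0.00086 upwards, adjusted p = 0.676 with an estimated correlation).

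Between 2 years and 4 weeks, limma called 254 genes, 104 higher and 150 lower at 2 years. The share higher at 2 years was 40.9% as deposited, 67.4% with the log2 of the mean and 20.4% with no filter on low values. It was 69.7% without 2-year preparation 1, 28.6% without 2-year preparation 2 and 19.8% without 4-week preparation 2. In percent of the reported count, 27.6% as many genes were called without 2-year preparation 2 and 65.4% without 4-week preparation 1. Without 2-year preparation 2 the calls ended for Adarb2, Arc, Calb1, Camk2a, Cck, Fosl2, Gabra5, Gabrd, Grin2a, H2-D1, H2-K1, Lamp5 and Trpc6. Without 4-week preparation 2 they ended for Adarb2, Camk2a, Gabra5, Gabrd, Grin2a, H2-D1 and Trpc6, and without 4-week preparation 1 for Adarb2, Fosl2 and Lamp5. Without 2-year preparation 1 or any 1 DG preparation the calls that ended were among Adarb2, Camk2a, H2-D1, H2-K1 and Trpc6. Of the 34 called genes named for this comparison, 13 lost the call with the log2 of the mean, Camk2d, Necab3, Nptx2 and Dpysl3 among them, and 14 with no filter on low values.

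Between 2 years and 12 weeks the median of all genes lay at 0.15, and differences are given relative to it. SEs, p-values, means and counts are again from before the shift. Camk2d, a calcium-dependent kinase (chromosome 3, 126596302 to 126846326), was higher at 2 years by 3.98 (SE 0.41, limma adjusted p = 1.15e-07, n = 2 against 4), with means of 4.88 ± 0.16 (SD, n = 2) and 0.75 ± 0.07 (SD, n = 4). The transcriptional inhibitor gene Id2 was higher by 3.63 (SE 0.58, limma adjusted p = 0.000877), with means of 5.42 ± 0.14 and 1.64 ± 0.89. The neurexin gene Nrxn3 was higher by 2.92, the histone gene H2afz by 2.55 and the translation-associated gene Tpt1 by 2.48. Lypd1, which modulates nicotinic receptors, was lower at -3.71 (SE 0.65, limma adjusted p = 0.00934), with means of 4.19 ± 0.03 and 7.75 ± 0.93. The preparations of both ages did not overlap for these genes, and cluster 4 held 11 of the 2-year nuclei.

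Of the lists, camera placed ribosomal protein genes and oxidative phosphorylation genes higher at 2 years than at 12 weeks, with 0 members past the limma threshold in each. The ribosomal protein gene Rpl36al and the ATP synthase gene Atp5l, which are not in these lists, were called higher. Both calls ended with the log2 of the mean, without DG preparation 2 or 3 and without 2-year preparation 1. Ribosomal protein genes had 13 of 36 higher adjusted over the list alone and 18 at an unadjusted p under 0.05 (camera adjusted p = 2.6e-10, adjusted p = 0.585 with an estimated correlation), with Rpl18 at 2.08 (limma adjusted p = 0.148). Oxidative phosphorylation genes had 10 of 41 higher adjusted over the list alone and 16 at an unadjusted p under 0.05 (camera adjusted p = 4.69e-09, adjusted p = 0.685 with an estimated correlation), with Ndufa9 at 1.88 (limma adjusted p = 0.115). Before the shift is taken off, the median of the ribosomal list was 1.16 as deposited, 0.57 with the number of detected genes as a covariate and 0.28 with the log2 of the mean. That of the oxidative phosphorylation list was 1.06, 0.48 and 0.30. Cluster 5 had Ndufs5 and Rps10 among its leading genes and a median of 5901 genes, the most of the granule-like clusters. It held 14 and 29 nuclei of the 2-year preparations, and 15, 3, 14 and 10 of DG preparations 1 to 4. Ionotropic glutamate receptor genes lay lower, with 0 of 13 by limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0018, adjusted p = 0.585 with an estimated correlation), and Grid1 at -1.41. Immature neuron genes lay lower, with 0 of 17 by limma, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0351, adjusted p = 0.585 with an estimated correlation), and Stmn2 at -1.53. Calcium and sodium channel genes lay lower, with 0 of 19 by limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0351, adjusted p = 0.749 with an estimated correlation).

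Between 2 years and 12 weeks, limma called 15 genes, 14 higher and 1 lower. With the log2 of the mean it called 0, where 9.24% of the tested genes had an unadjusted p under 0.05. The share of called genes higher at 2 years was 93.3% as deposited, 66.1% after quantile normalization, 28.9% with the number of detected genes as a covariate and 50% without 2-year preparation 2. The count was 48 and 23 without 4-week preparations 1 and 2, 6, 8, 5 and 7 without DG preparations 1 to 4, and 5 and 34 without 2-year preparations 1 and 2. Camk2d and Id2 held with each of these left out, and Lypd1 lost its call without DG preparation 3 or 2-year preparation 1. The calls for H2afz and Tpt1 ended without any 1 DG preparation or 2-year preparation 1, and that for Nrxn3 without DG preparation 1, 3 or 4 or either 2-year preparation. With recovered depth as a covariate, or with no filter on low values, Camk2d alone of the 9 named genes stayed past the threshold. With the preparation number as a replicate block, Camk2d and Id2 did.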

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

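The tests of a difference of all 4-week nuclei, of an unlabelled region, of the GABAergic-like share in the sorted pool, of cluster 1 alone, of Syne2 in DG alone and of free Ttr RNA were chosen after the result was seen. Among 234 sets of 4 DG preparations looked at, 14 held a preparation far from the other 3, where chance flags about 1 in 20 groups (11.7 here). In the region comparison, DG preparation 1 was the lowest for Adcy1 (8.57, median of the others 10.47) and Ncald (9.25) and the highest for Sez6 (4.04) and Spock1 (1.53). Of its 135 nuclei 19 were pyramidal-like, against 0 of 40, 1 of 72 and 3 of 58 in preparations 2 to 4. That class had 0 own markers among the leading genes of its clusters. Preparation 4 was the highest for Fos (0.19). In the sorted comparison, preparation 2 was the lowest for Hspa8 (10.38), and preparation 1 the lowest for Maml2 (5.47) and Pcp4 (7.14). In the age comparison, preparation 4 was the lowest for Col27a1 (0) and the highest for H2afz (7.17), and preparation 2 was the lowest for Gabra5 (4.85), Rpl7 (6.98) and Tpt1 (5.81) and the highest for Grid1 (4.82). The 22 sorted CA nuclei, which entered none of the fits across genes, had a mean of 4.93 over GABAergic neuron markers, above all 4 unsorted CA preparations (1.05 to 1.67).

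Granule-like nuclei at 4 weeks stood apart from those at 12 weeks in 1071 genes. Depth as the whole cause is argued against: with recovered depth as a covariate the median absolute log2 difference of these genes was 104% of that without (2.13 against 2.04) and 99.8% kept their sign, while fewer passed because the median SE grew from 0.536 to 0.869. Another region in the set with no region label is argued against as the whole cause, since the sets labelled DG alone gave 134% of the reported count (n = 4 against 1), though of the genes called without the 4-week set labelled DG, where 97.7% had the same sign, 74.1% reached 0.5 of the fold in that set. A difference of all 4-week nuclei, as a library batch would give, cannot be told apart from age: other classes followed with an average slope of 0.492, from 0.197 in pyramidal-like to 0.751 in astrocyte-like nuclei, in 1 to 3 preparations per class and age. Maturation of granule neurons, the difference in age that the design names, may account for the rest and remains untested against that batch.

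VGAT DG nuclei differed from unsorted DG nuclei in 2943 genes. The larger share of GABAergic-like nuclei is argued against as the whole cause for the called genes still tested without them. Over these genes the median absolute log2 difference was 94.7% of its value (1.89 without them). Genes no longer tested, 7 of the 59 named ones among them, are not covered, and the GABAergic-like share may account for those. Recovered reads were not lower in VGAT DG, with medians of 75413 and 84275.5 against 52524 to 90005.5 in unsorted DG. Recovered depth as a covariate, which left 97.7%, could thus hardly move the difference. With the number of detected genes as a covariate, 28.4% as many genes were called. A difference of all sorted nuclei, from virus, strain, sort or library batch, goes with a slope of 0.763 of the difference in GABAergic-like on that in granule-like nuclei. Of the genes, 81.9% had 1 sign in both. In astrocyte-like nuclei, which came from VGAT DG preparation 1 alone, the slope was 1.098. Both classes hold unlike subgroups, as cluster 1 held 73.7% of the granule-like nuclei in VGAT DG and 17.8% in unsorted DG. Within it the median absolute log2 difference was 55.2% of that in all granule-like nuclei (0.98 against 1.78, Zfp949 5.65 against 6.35). The slope of GABAergic-like nuclei on cluster 1 was 0.858. Cluster 1 was found from these same values with the sorted nuclei included, so a smaller difference within it was partly built in and decides nothing. The injected tag carries a KASH domain, a piece of a nesprin, and reads of it counted as Syne2 are a candidate explanation for that gene: within GABAergic-like nuclei Syne2 differed by 3.36 (5.05 ± 1.98, SD, n = 3 from DG and CA, against 1.69 ± 1.09, SD, n = 8 from DG, CA and 2 years with as few as 2 nuclei, two-sided exact permutation p = 0.00606), in DG alone by 3.58 (n = 2 against 3), and within granule-like nuclei of DG by 4.23. Virus, strain, sort, batch and subgroups change together in this design, so their parts cannot be told apart, and no biological explanation was tested.

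Ttr, the transthyretin gene abundant in the choroid plexus (chromosome 18, 20665280 to 20674321), averaged 11.44 on the log2(value + 1) scale in CA2/3 preparation 3 and 7.04 in CA1 preparation 3, with 4.60 in the sorted CA nuclei and at most 1.35 in every other preparation. Free RNA taken up by all nuclei alike is consistent with shares of nuclei with Ttr of 78.6% in granule-like, 88.3% in pyramidal-like, 100% in GABAergic-like and 76.5% in glial-like nuclei, at most 13.9 percentage points from the share over all of them. For whole choroid plexus cells or nuclei among the sorted ones the test was undecided, since the most frequent of 4 other choroid plexus genes, Kl, reached 25.3% of the share of Ttr. Kl was also found in 33.9% of the nuclei of CA1 preparation 1, where Ttr averaged 0, so it did not mark choroid plexus here. In the CA preparations numbered 3, Clic6 was found in 10.9%, Kcne2 in 4.95% and Folr1 in 1.98% of nuclei, and Ttr in 86.1%. These shares argue against whole cells as the source of Ttr in most of these nuclei. They leave whole cells open for a part of them, as Clic6 was found in 16.4% of CA2/3 preparation 3 and 2.5% of CA1 preparation 3. No biological explanation was tested.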

How the results depend on the processing

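Settings added after seeing the data were rescaling to TPM totals, the minimum of 4000 genes, recovered depth, the class-matched comparisons, the preparations numbered 3 left out, thinning and fry in either direction. Counts of called genes are given in percent of the reported count. Outside 1.5 times it they were as follows, and where nothing else is said the cause was not tested. With the log2 of the mean they were 19.7% for DG against CA1, 15.2% for DG against CA2/3, 0% for CA1 against CA2/3 (limma, 5.88% of genes at an unadjusted p under 0.05), 41.05% for sorted DG, 50.8% for 2 years against 4 weeks, 0% for 2 years against 12 weeks (limma, 9.24%) and 59.5% for 12 against 4 weeks. With no filter they were 173.7% for CA1 against CA2/3 and 13.3% for 2 years against 12 weeks. With fewer genes tested under the filter at 50% they were 64.2% for DG against CA1, 10.53% for CA1 against CA2/3, 52.8% for 2 years against 4 weeks and 64.9% for 12 against 4 weeks. Quantile normalization gave 152.6% for CA1 against CA2/3, 178.7% for 2 years against 4 weeks and 393.3% against 12 weeks. The number of detected genes as a covariate gave 202.9% for DG against CA2/3, 852.6% for CA1 against CA2/3, 28.4% for sorted DG, 209.8% for 2 years against 4 weeks and 1153% against 12 weeks. The preparation number as a replicate block gave 57.8% for DG against CA1, 52.9% for DG against CA2/3, 47.3% for sorted DG, 46.7% for 2 years against 12 weeks and 40.9% for 12 against 4 weeks. The labels do not say that this number pairs samples, and deviations from the group means correlated across genes, which are not independent replicates, at -0.000306 for DG and CA1 preparations 1 and at 0.414 for CA1 and CA2/3 preparations 1.

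All nuclei gave 26.3% for CA1 against CA2/3, 58.3% for 2 years against 4 weeks and 46.7% against 12 weeks. The minimum of 4000 genes gave 47.4% for CA1 against CA2/3, 159.8% for 2 years against 4 weeks and 353.3% against 12 weeks. Recovered depth gave 21.1% for CA1 against CA2/3, 33.3% for 2 years against 12 weeks and 38.9% for 12 against 4 weeks. Rescaling to TPM totals gave 60% and the sets labelled DG alone 520% for 2 years against 12 weeks. Granule-like against pyramidal-like nuclei gave 159.6%, 203.7% and 252.6% for DG against CA1, DG against CA2/3 and CA1 against CA2/3, and without the preparations numbered 3 these were 193.2%, 291.0% and 1074%. Granule-like nuclei alone gave 61.98% for sorted DG. With 1 preparation left out at a time the ranges were 48.4% to 153.6% for DG against CA1, 37.9% to 161.9% for DG against CA2/3, 10.53% to 389.5% for CA1 against CA2/3, 55.5% to 102.1% for sorted DG, 27.6% to 139.0% for 2 years against 4 weeks, 33.3% to 320.0% against 12 weeks and 53.8% to 119.6% for 12 against 4 weeks. The excess of excitatory-like nuclei in DG ranged from 15.4 to 21.4 percentage points (exact permutation p = 0.0571 without any 1 CA preparation) and was 11.99 in nuclei with at least 4000 genes. With 1 preparation left out, glial-like nuclei ranged from -15.3 to -12.3 (-7.01 in nuclei with at least 4000 genes, -13.6 reported) and GABAergic-like from -6.10 to -3.14. Of 188 tests of lists, 57 passed camera, 0 with an estimated correlation (20 at an unadjusted p under 0.05) 40 fry and 107 fry in either direction. All other settings left the counts within 1.5 times and the tests of shares on their side of the threshold, and the minimum of 2000 genes removed no nucleus. Of 4691 values of the 221 named and called genes under other settings, 4187 kept direction and call, 504 kept the direction alone and 0 reversed. The genes were named for their differences in these same data, so this was largely fixed beforehand. Where preparations do not overlap, leaving out 1 of them cannot reverse the sign. The minimum of 2000 genes and the loss of a preparation outside a comparison leave the fold as it was. Depth limits the shares of rare markers: after thinning, or with values above 10, 73 shares stayed within the spread and 7 moved.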

Other observations

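The test of this part, the second clustering, was chosen before the data were examined. Clustered again, the 112 GABAergic-like nuclei fell into 4 groups. The largest, of 33 nuclei, scored highest for neurogliaform or ivy interneurons, with Lamp5 and Lhx6 among its leading genes, and held 23 nuclei of VGAT DG preparation 1, 1 of preparation 2 and 2 of the sorted CA nuclei. A group of 32 nuclei scored highest for interneurons from the caudal ganglionic eminence. Of those markers Adarb2 alone was among its 10 leading genes, and Adarb2 was also found in 30 of 43 granule-like nuclei of VGAT DG preparation 1. This group was led by the transcription factor gene Npas1 and held 10 and 8 nuclei of VGAT DG preparations 1 and 2 and 8 of the sorted CA nuclei. A group of 23 nuclei carried markers of interneurons from the medial ganglionic eminence, with Satb1 among its leading genes. It held 8 of the sorted CA nuclei, 3 of VGAT DG preparation 1 and 3 of preparation 2. A group of 24 nuclei, with 10, 3 and 1 from unsorted DG preparations 1, 3 and 4, scored highest for somatostatin interneurons, but 0 of those markers were among its 10 leading genes. It held 1 nucleus each of VGAT DG preparations 1 and 2 and 0 of the sorted CA nuclei. Its leading genes included Cck and the oxidative phosphorylation genes Ndufa4 and Cox5b. Cck and the oxidative phosphorylation list were lower in VGAT DG than in unsorted DG. For this group, subtype cannot be told apart from sort or batch.

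Over the 22 sorted CA nuclei, averages of 23 of 30 lists lay below the range of the unsorted CA preparations, in the preparation with the lowest median of genes (3732.5) and of recovered reads (47261). Among them were excitatory neuron markers (1.01 against 3.12 to 4.68), CA1 markers (0.81 against 1.14 to 3.98), heat shock and stress genes (2.40 against 4.20 to 5.57) and oxidative phosphorylation genes (2.89 against 4.75 to 7.91). Interneuron subtype markers averaged 1.83, within 1.44 to 2.24.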
